A study of Mus musculus with 4 samples.

How the data were processed

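The series holds 4 single-cell RNA libraries of mouse cells sorted as CD138+ B220-, a surface profile of plasma cells. Per the labels, cells were isolated in droplets on the Bio-Rad ddSEQ instrument and turned into libraries with Illumina's SureCell 3′ whole-transcriptome kit, which counts transcripts at their 3′ end with a molecular identifier (UMI). The deposited tables, as the authors made them, hold raw UMI counts per gene and cell for cells past the authors' knee filter on cell barcodes, with no scaling. The genome build was mm10 per the submitters' processing notes. Each table has 24421 gene columns. No column is an immunoglobulin chain gene and none is a mitochondrially encoded gene, so the heavy chain constant list, the mitochondrially encoded list and the dominant immunoglobulin genes are not analysed here. Gene coordinates come from the GENCODE vM21 annotation of GRCm38, in which 195 of the 196 named genes were found.

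The 781 cells were clustered together with scanpy 1.11.5 on log-normalised counts, using 1998 highly variable genes, 20 principal components, 15 neighbours and Leiden resolution 1.0. Cell type markers were fixed before the data were examined, and the rules that turn them into names and retained clusters were set after the clusters were seen. A cluster was retained when at least 8 of the 13 measured plasma cell markers had a UMI in at least 25% of its cells, unless its cells had a median under 0.333 of their own library's median UMIs and no plasma cell marker among its top 10 genes. A retained cluster was named plasma cell-like unless another type had more markers than plasma cells among its top 10 genes. A cluster with fewer plasma cell markers took the name of the type with at least 3 markers among its top 50 genes. These rules kept 5 clusters, 4 of them named plasma cell-like. They left out the B cell precursor-like, T cell-like and neutrophil-like clusters and a low-UMI cluster in which 9 of the 13 markers were detected. Because plasma cell markers took part in the choice of cells, their level in the retained cells is not independent of that choice. The comparisons, gene lists, test and rule for named genes were fixed before the data were examined.

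Counts of retained cells were summed per library, and cells were never treated as replicates. The sums were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and the quasi-likelihood test, all 4 libraries in a single fit of 3 group means. The filter left 8219 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE given with a log2 fold change is its absolute value over the square root of the test's F statistic. It is thus computed back from the test and holds no measured spread of the single-library groups. The fit has 1 residual degree of freedom, from the VQ bone marrow pair, and the single wild-type and lymph node libraries are assumed to vary like that pair. The labels do not state whether the pair came from different animals, so each p measures only the spread between these 2 libraries, which may be technical. The pair differed by more than counting noise (chi-square over degrees of freedom 1.50 across 7493 genes, p = 2.63e-158 by an asymptotic chi-square test), which excludes a repeated deposit of 1 library, the case that the rule set beforehand asks about. It does not show that the pair came from 2 animals, since sums over different cells would also differ in this way. The common biological coefficient of variation was 0.0819 and its prior degrees of freedom were infinite, so 1 spread trend served every gene. Tested on simulated counts with the depths of these libraries and the spread of the VQ bone marrow pair, 44 of 100 genes with a 2-fold change and 96 of 100 with a 4-fold change were called between VQ and wild-type bone marrow, with 6 false calls among 146. Between lymph node and VQ bone marrow, the same test called 88 and 100 of 100, with 8 false calls among 196. The changed genes were drawn only from those above a minimum expected count in the smallest library. The recovered numbers therefore do not cover tested genes with lower counts. All 4 libraries were drawn with that same spread and, apart from the changed genes, the same composition. The false calls thus do not show whether the single libraries vary like the pair.

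Expression is given as TMM-scaled CPM (counts relative to the library's scaled total) of the summed retained cells, with the SD over the 2 VQ bone marrow libraries. Wild type and lymph node have no replicate. A gene with 0 counts in 1 group has a fold given as a bound against a floor of 3 counts over that group, and other folds have a 95% counting interval. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 is given a limit of 3 over the number of cells. Intervals and floors cover counting error only. The 3 comparisons were VQ bone marrow against wild-type bone marrow, VQ lymph node against VQ bone marrow, and VQ lymph node against wild-type bone marrow.

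The lists fixed beforehand cover plasma cell identity, B cell genes, germinal centre genes, MHC class II, MHC class I presentation, MYC targets with ribosome biogenesis, RAS and MAPK output, proliferation, the unfolded protein response with secretion, the integrated stress response with amino acid supply, interferon response, survival, cytokine receptors, homing, immune checkpoints, myeloma oncogenes, glycolysis, oxidative phosphorylation, ribosomal proteins, the proteasome, and immediate early with heat shock genes. Further lists cover sex-linked genes and RNA of red cells (haemoglobin), neutrophils, T and NK cells, macrophages and stroma. Each list is described by the number of tested members called, by the number called when p is adjusted over the list alone, and by its median log2 fold change with the percentile of that median among 10000 random lists matched on expression in 20 bins. Genes were named by rule: the first 12 called rises and first 12 called falls per comparison, ranked by fitted log2 fold change, which favours genes with 0 counts in a group, among genes of at least 50 CPM in the higher group, with both VQ bone marrow libraries on the same side, genes such as Myc, Nras, Sdc1 and Ptprc as checks of the labels, and up to 4 members of each list with the largest change. Immunoglobulin, mitochondrial, ribosomal protein and predicted genes were left out of the ranked part. Where 5 or fewer genes of a list were called, all are named. Any gene named outside the rule was chosen after its values were seen and is introduced as such.

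Alternatives planned beforehand were size factors (RLE) in place of TMM, library totals as the only scaling, DESeq2 1.42.0, no filter on low counts, all cells of each table, cells without UMIs of 9 cycle genes, removal of doublets called by Scrublet, sums thinned to the smallest library, only the libraries of the comparison, leaving out each VQ bone marrow library, the mean of per-cell CPM, other Leiden resolutions, and other minimums for proliferation genes. Alternatives added after the data were seen were a preset biological coefficient of variation of 0.4, only the clusters named plasma cell-like, removal of the cluster shared by wild-type and VQ bone marrow, only cells of at least 1000 UMIs, and library totals without Jchain. Figures were drawn with matplotlib 3.10.9, and intervals were computed with scipy 1.17.1 in Python 3.11.15.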

Results

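Plasma cells, sorted as CD138+ B220-, were profiled from wild-type mouse bone marrow (1 library), from the bone marrow of mice carrying VQ-D2 myeloma (2 libraries) and from a lymph node of the same model (1 library). Per the labels, the VQ cells are donor-derived myeloma cells that carry a Vκ*MYC transgene, a conditional mutant Nras allele and IgG1-Cre, and were taken from recipient animals. The wild-type library held 163 cells and 340253 UMIs, with a median of 2021 UMIs (counted transcripts) per cell. VQ bone marrow replicate 1 held 245 cells and 1066884 UMIs (median 4386), and replicate 2 held 188 cells and 457158 UMIs (median 2352). The lymph node library held 185 cells and 803752 UMIs (median 3978). Whether the lymph node and bone marrow cells came from the same animal is not stated.

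The retained clusters, in which most plasma cell markers were detected, held most cells of every library: 125 of 163 in wild type (76.7%, 95% interval 69.4 to 82.9), 206 of 245 in VQ bone marrow replicate 1 (84.1%, 78.9 to 88.4), 136 of 188 in replicate 2 (72.3%, 65.4 to 78.6) and 158 of 185 in the lymph node (85.4%, 79.5 to 90.2). With a coarser clustering the shares were 80.4% in wild type and 96.3%, 96.3% and 100% in the VQ libraries. These numbers of cells match the inclusion of the low-UMI and T cell-like clusters described below. The retained sums held 227216 UMIs in wild type, 1023581 and 402879 in the VQ bone marrow libraries and 771018 in the lymph node. B cell precursor-like cells, led by Dntt and Rag1, the enzymes of immunoglobulin gene rearrangement, were 29 of 163 wild-type cells (17.8%, 12.3 to 24.5), 2 of 245 in VQ bone marrow replicate 1, 0 of 188 in replicate 2 and 0 of 185 in the lymph node (limit 1.62%). T cell-like cells numbered 2, 11, 5 and 1 in the same order of libraries, and neutrophil-like cells 3, 7, 7 and 0. A low-UMI cluster that carried plasma cell markers but was left out for its depth held 4 wild-type cells, 19 and 40 cells of the VQ bone marrow libraries and 26 lymph node cells. Retained wild-type cells were of 2 main kinds. A cluster in which H2-Aa and H2-Ab1 ranked among the top 10 genes held 74 of the 125 and took no cell type name under the marker rule, and a cluster rich in Jchain held 48. Jchain was high in both, at 158299 CPM in the first and 219319 CPM in the second, without TMM scaling. The second, with Jchain among its top 10 genes, is called the Jchain-rich cluster here. Wild-type cells of clusters named plasma cell-like were 51 of 163 (31.3%, 24.3 to 39.0). The Jchain-rich cluster also held 23 and 21 cells of the VQ bone marrow libraries and none of the 158 retained lymph node cells.

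The share of cells with UMIs of proliferation genes depended on the mark used, and was above wild type in each VQ library at all 4 marks. Retained cells were thinned to 500 UMIs, and those with fewer were left out. This kept 112 of 125 wild-type cells, 129 of 136 cells of VQ bone marrow replicate 2 and all cells of the other libraries. At least 2 of the 48 measured proliferation genes then had a UMI in 169 of 206 cells of VQ bone marrow replicate 1 (82.0%, 95% interval 76.1 to 87.0), in 91 of 129 cells of replicate 2 (70.5%, 61.9 to 78.2) and in 112 of 158 lymph node cells (70.9%, 63.1 to 77.8). In wild type, 9 of 112 cells met this mark (8.04%, 3.74 to 14.7). The wild-type share was 34.8% with at least 1 gene, 0% with at least 3 and 40.8% without thinning, against 86.0 to 91.7%, 54.4 to 62.6% and 86.8 to 97.5% in the VQ libraries. Within the Jchain-rich cluster the counts were 5 of 44 wild-type cells (11.4%), 5 of 23 cells of VQ replicate 1 (21.7%) and 3 of 17 of replicate 2 (17.6%). No difference between these shares was tested, since each library gives 1 value.

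The first comparison asks how VQ myeloma cells of the bone marrow differ from wild-type bone marrow cells sorted as plasma cells. Myc, the oncogenic transcription factor driven by the transgene of this model, was 29.6-fold higher in VQ cells, and genes of ribosome biogenesis and cell division rose. Against this, most plasma cell identity and antigen presentation genes fell, as did 11 of 20 immediate early and heat shock genes. Jchain, the joining chain of polymeric antibodies, was 22.3-fold lower and Mzb1, a chaperone of antibody assembly in the endoplasmic reticulum, 62.5-fold lower. Without the Jchain-rich cluster, the log2 fold changes went from -4.47 to -5.06 for Jchain and from -5.91 to -7.38 for Mzb1. That setting removes wild-type as well as VQ cells. It leaves 77 of the 125 retained wild-type cells, 74 of them in the cluster with H2-Aa and H2-Ab1 among its top genes. Of 8219 genes tested with edgeR, 1414 were higher and 1098 lower in VQ bone marrow, 1108 and 944 of them by at least 2-fold.

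Myc (chromosome 15, 61985391 to 61990374) stood at 41.7 CPM in wild type and at 1263 ± 95.3 CPM (SD, n = 2) in VQ bone marrow, a log2 fold change of 4.91 (SE 0.34, edgeR adjusted p = 4.84e-44). The tables do not say whether transcripts of the transgene are counted under Myc. Nras (chromosome 3, 103058285 to 103067914), the small GTPase altered in this model, stood at 93.9 CPM in wild type and 286 ± 14.5 CPM (n = 2) in VQ bone marrow (log2 1.59, SE 0.33, edgeR adjusted p = 1.89e-05). That call was lost with the preset coefficient of variation, cells without cycle genes and thinned sums. Sdc1, which encodes the CD138 used for sorting, was slightly lower, at 991 against 645 ± 60.5 CPM (log2 -0.61, edgeR adjusted p = 0.00531), a call that was lost with DESeq2, library totals, the preset coefficient of variation, the clusters named plasma cell-like, cells without cycle genes, all cells and thinned sums. Ptprc, which encodes the B220 antigen and CD45, was 3.06-fold lower (interval 2.15 to 4.28), a call lost with the preset coefficient of variation, the clusters named plasma cell-like and thinned sums.

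Of 47 tested proliferation genes, 44 rose and 0 fell (45 and 0 adjusted over the list alone). Their median log2 fold change was 4.30, or 2.63 with 16 genes at their bound, above all 10000 matched random lists. Ccna2, cyclin A2 of S and G2 phase, had no UMI in wild type and was at least 19.9-fold higher. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at least 12.5-fold higher, Cdk1, the mitotic kinase, at least 9.04-fold and Birc5, survivin, at least 8.50-fold. Of 49 tested MYC targets and ribosome biogenesis genes, 42 rose and 0 fell (43 and 0 adjusted over the list alone), with a median of 1.77 at percentile 100. Apex1, a DNA repair endonuclease, rose 17.5-fold (interval 4.81 to 146), Grwd1, a ribosome assembly factor, 9.15-fold (2.49 to 76.3), and Nop56, a core protein of nucleolar particles, 7.13-fold (2.75 to 26.4). The calls of Grwd1 and Nop56 were lost with the preset coefficient of variation, the clusters named plasma cell-like, cells without cycle genes and thinned sums. That of Grwd1 was also lost with DESeq2, and that of Nop56 with all cells. Ribosomal protein genes rose more modestly. Of 75 tested, 41 were higher and 1, Rps24, named after its values were seen, lower (42 and 1 adjusted over the list alone), with a median of 0.52 at percentile 97.8. Rps2 rose by 1.87 on the log2 scale and Rpl22l1 by 1.97.

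RAS and MAPK output genes moved in both directions. Of 10 tested, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 4.81, or 1.44 with 5 genes at their bound. Etv5, a transcription factor induced by MAPK signalling, was at least 6.90-fold higher, Spry4, a feedback inhibitor of the pathway, at least 4.71-fold, and Phlda1 rose 12.4-fold (interval 4.82 to 45.8). Egr1 fell by 2.89 on the log2 scale and Dusp1, a MAPK phosphatase named after its values were seen, by 1.57 (0.04 with the clusters named plasma cell-like, not called). The call of Egr1 was lost among cells without cycle genes. Egr1 and Dusp1 also belong to the immediate early and heat shock list, in which 11 of 20 tested genes fell and 3 rose (11 and 3 adjusted over the list alone; median -1.34, below all random lists). Hspa1a, an inducible HSP70 chaperone, was 137-fold lower (interval 51.0 to 516) and Hspa1b 81.1-fold lower (45.8 to 156). Fosb and Junb, subunits of AP-1, fell by 3.43 and 2.92 on the log2 scale. The 3 that rose were the chaperones Hspa8, Hsp90ab1 and Hspe1, named after their values were seen, by 0.77, 0.82 and 1.18.

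Among 20 tested plasma cell identity genes, 16 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -1.42, below all random lists. With only the clusters named plasma cell-like, 10 fell and 2 rose, with a median of -0.76. Jchain (chromosome 5, 88519809 to 88527891) took 12.4% of all UMIs in the wild-type library and 1.01% and 1.00% in the VQ bone marrow libraries. Its level was 218580 CPM in retained wild-type cells and 9869 ± 213 CPM (n = 2) in VQ bone marrow (log2 -4.47, SE 0.14, edgeR adjusted p = 3.20e-214). Mzb1 (chromosome 18, 35647267 to 35649367) stood at 5964 against 108 ± 39.3 CPM (log2 -5.91, SE 0.18, edgeR adjusted p = 5.83e-218). Tnfrsf17, the BCMA receptor that sustains plasma cells, was 7.25-fold lower (interval 5.45 to 9.64) and Prg2, a granule protein also made by plasma cells, 35.9-fold lower (28.6 to 45.4). The 2 genes that rose, named after their values were seen, were Ly6c1 and Ly6c2, which encode related surface antigens, by 2.69 and 1.89 on the log2 scale.

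More secretion genes fell than rose. Of 44 tested genes of the unfolded protein response and secretion, 26 fell and 5 rose (26 and 5 adjusted over the list alone), with a median of -0.69, below all random lists. With library totals as the only scaling 19 fell and 9 rose (median -0.35), with the clusters named plasma cell-like 21 and 3, with DESeq2 18 and 3, among cells without cycle genes 18 and 2, and with a preset coefficient of variation 4 and 1. Herpud1 and Edem2, both of endoplasmic reticulum degradation, were 5.69-fold (interval 5.08 to 6.37) and 4.93-fold (4.11 to 5.89) lower. Subunits of the same translocon-associated complex went opposite ways: Ssr4 was 4.21-fold lower (3.87 to 4.58), and Ssr2 was 6.10-fold higher (5.08 to 7.40). The other 4 that rose, Edem1, Pdia6, Ssr1 and Fkbp11, were named after their values were seen and rose by 0.41 to 1.34 on the log2 scale. The integrated stress response and amino acid supply list was split, with 6 of 22 tested genes higher and 5 lower (7 and 5 adjusted over the list alone, median 0.23). Ddit3, the stress factor CHOP, fell by 4.67 on the log2 scale and Slc3a2, a shared chain of amino acid transporters, by 3.38, while Psat1, an enzyme of serine synthesis, rose by 2.24. The call of Psat1 was lost with the preset coefficient of variation. The other 3 that fell were Ppp1r15a, by 2.42, and the transcription factors Atf4 and Atf5, named after their values were seen, by 0.89 and 1.73. With the clusters named plasma cell-like the call of Ppp1r15a was lost.

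Antigen presentation genes fell. Of 7 tested MHC class II genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone; median -5.21). H2-Aa was 208-fold lower (interval 78.9 to 778), H2-Ab1 56.0-fold (38.5 to 83.8), H2-Eb1 38.2-fold (25.1 to 60.1) and H2-Ob at least 68.7-fold. Cd74, the invariant chain, named after its values were seen, fell by 4.74 on the log2 scale. The wild-type cluster with H2-Aa and H2-Ab1 among its top genes holds 74 of the 125 retained wild-type cells, and with only the clusters named plasma cell-like, 3 of 5 tested MHC class II genes were lower, with a median of -4.08. Of 12 tested genes of MHC class I presentation, 9 fell and 0 rose (10 and 0 adjusted over the list alone; median -1.35, percentile 0.01). B2m, the invariant light chain of class I, went from 27507 to 2541 ± 325 CPM (log2 -3.44, edgeR adjusted p = 1.90e-123), and the heavy chain H2-K1 fell by 2.33 on the log2 scale. In the interferon response list, 11 of 25 tested genes fell and 3 rose (11 and 3 adjusted over the list alone; median -1.19, below all random lists). Without the Jchain-rich cluster the median was -0.40, with 10 lower and 3 higher. That setting also leaves out 48 of the 125 retained wild-type cells, so the wild-type side changes too. Ly6a, the interferon-inducible antigen Sca-1, was 71.1-fold lower (56.8 to 90.1), and Ifitm3, an antiviral membrane protein, rose 6.20-fold (2.98 to 15.5). The call of Ifitm3 was lost with the preset coefficient of variation. The GTPases Gbp3 and Gbp7, named after their values were seen, rose by 2.20 and 1.80 on the log2 scale. Of 9 tested B cell genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -3.15). With only the clusters named plasma cell-like, 2 of 6 fell and 0 rose, with a median of -0.96. Ms4a1, which encodes CD20, was 127-fold lower (19.7 to 5317) and the transcription factor Irf8 was 27.7-fold lower (13.4 to 62.8). The call of Irf8 was lost with the clusters named plasma cell-like. The gene that rose was Bach2, named after its values were seen, at least 1.85-fold (log2 -0.89 with all cells, not called).

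Outside these groups, several genes with no UMI in wild type rose. Tex101 (chromosome 7, 24668007 to 24676675), a glycoprotein best known from germ cells, was at least 41.5-fold higher, with 702 and 285 UMIs in the VQ bone marrow libraries (edgeR adjusted p = 2.85e-35). Crygs, a lens crystallin, was at least 18.3-fold higher, Arg1, arginase, at least 14.5-fold, Slc16a1, a lactate transporter, at least 11.8-fold and Syce2, a protein of the meiotic synaptonemal complex, at least 11.3-fold. Fam162b, Oaf, Asph, Smpdl3b and Trps1 were each at least 10.6-fold higher. Falls included Slpi, a secreted protease inhibitor, at 6976 against 66.5 ± 8.38 CPM (log2 -6.75, or -10.94 without the Jchain-rich cluster, edgeR adjusted p = 1.50e-257), St8sia6, a sialyltransferase, 309-fold lower (interval 52.3 to 12516), and Hsd11b1, which regenerates active glucocorticoid, 135-fold lower (34.5 to 1157). Spon1, Acss1, Pitpnc1 and Cyp4v3 also fell.

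Immune checkpoint genes fell, and the survival, other surface and metabolic lists held called genes of both directions. Of 26 tested survival genes, 9 fell and 3 rose (9 and 4 adjusted over the list alone, median -0.50). Bcl2, which opposes apoptosis, fell by 4.15 on the log2 scale and the kinase Pim2 by 4.40, while Trp53inp1, a target of p53, fell by 4.19. Among cells without cycle genes the call of Bcl2 was lost. The 3 that rose, named after their values were seen, were the death effectors Bak1, Bbc3 and Pmaip1, by 4.08, 2.07 and 1.17. Homing genes fell in 9 of 21 and rose in 4 (9 and 5 adjusted over the list alone; median -0.73). With library totals 6 fell and 6 rose, and with the clusters named plasma cell-like 6 and 2 (median 0.05). The integrin chain Itgb7 was 49.1-fold lower (interval 18.9 to 162) and the adhesion molecule Epcam rose by 2.91 on the log2 scale. Itgb1, Klf2 and Itga6 also rose, and were named after their values were seen. Immune checkpoint genes fell in 6 of 10 and rose in 0 (6 and 1 adjusted over the list alone; median -1.29, percentile 1.57), or in 2 of 8 with the clusters named plasma cell-like (median -0.66). Cytokine receptor genes fell in 4 of 19 and rose in 3 (4 and 3 adjusted over the list alone). Btla, an inhibitory receptor, fell by 5.01 on the log2 scale, and Il5ra, a chain of the interleukin-5 receptor, rose by 2.91. The call of Btla was lost among cells without cycle genes. That of Il5ra was lost with DESeq2, the preset coefficient of variation and the clusters named plasma cell-like. Cd320 and Socs2 rose too, and Tnfrsf17, Tgfbr1, Il2rg and Stat3 made up the 4 that fell (Socs2, Il2rg and Stat3 were named after their values were seen). Cd320 lost its call with the preset coefficient of variation. Myeloma oncogenes rose in 6 of 29 and fell in 7 (6 and 7 adjusted over the list alone). Nfkb2 and Relb, of the alternative NF-κB pathway, fell by 3.25 and 3.60 on the log2 scale. The call of Relb was lost with the clusters named plasma cell-like. Glycolysis genes rose in 5 of 17 and fell in 2 (5 and 2 adjusted over the list alone; median 0.79, percentile 94.1). Ldha, lactate dehydrogenase, rose 6.11-fold (4.05 to 9.68), beside Slc16a1, Pdk1, Tpi1 and Pkm, while Aldoa and Hif1a fell (Tpi1, Pkm and Hif1a were named after their values were seen). Pdk1 lost its call with DESeq2, the preset coefficient of variation, the clusters named plasma cell-like, cells without cycle genes, all cells and thinned sums. Aldoa lost its call with the preset coefficient of variation. Oxidative phosphorylation genes rose in 15 of 73 and fell in 8 (15 and 8 adjusted over the list alone, median 0.15), and proteasome genes rose in 12 of 48 and fell in 4 (13 and 4 adjusted over the list alone, median 0.40). Higher and lower counts for these 2 lists were 29 and 2 and 20 and 3 with library totals, and 2 and 2 and 0 and 1 with DESeq2. With the preset coefficient of variation both lists had 0 calls. Psme2, Psmb1, Psmb8 and Psmb9 were the proteasome genes that fell, named after their values were seen. Germinal centre genes rose in 2 of 5 and fell in 1 (2 and 1 adjusted over the list alone), with a median of -0.18 that became 0.16 with library totals as the only scaling. Ung and Basp1 rose and Fas, a death receptor, fell by 3.58 on the log2 scale. The call of Fas was lost with the clusters named plasma cell-like, and DESeq2 called none of the 5.

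Few genes of the lists of other cell types passed the filter. The macrophage list summed to 2197 CPM in wild type, 546 and 598 CPM in VQ bone marrow and 653 CPM in the lymph node. Of that list, 3 genes were tested and 1, Ctss, fell (1 adjusted over the list alone), and of the neutrophil list the 1 gene tested, S100a9, named after its values were seen, was 7.04-fold lower (interval 2.36 to 20.6; 1 adjusted over the list alone). The 1 tested gene of the T and NK cell list, Gzma, was not called, and no haemoglobin or stromal gene was tested. Among 3 tested sex-linked genes, 2 fell and 0 rose (2 and 1 adjusted over the list alone). Ddx3y and Eif2s3y of the Y chromosome were at least 111-fold and 52.8-fold lower in VQ bone marrow, with no UMI in either VQ library. The sex of the animals is not stated, and it may differ between wild type and VQ along with genotype. The missing Y-linked RNA does not show that the myeloma cells are female. In VQ bone marrow cells with little Jchain, Xist, the RNA of the inactive X chromosome, named after its values were seen, was also scarce. Its upper limit was 10.4 CPM without TMM scaling, against 445 CPM (interval 254 to 723) in cells of other types there. The sex-linked list, Xist included, summed to 0 CPM in retained lymph node cells. The reason was not tested.

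With a preset coefficient of variation of 0.4, 252 genes were higher and 280 lower, and of the MYC targets 3 rose and of the ribosomal protein genes 0; DESeq2 called 267 and 287, and the clusters named plasma cell-like alone gave 614 and 372, and sums thinned to the smallest library 0 and 1 with edgeR (964 and 955 at unadjusted p under 0.05). Of the calls, 56.3% were higher, a share that became 73.0% with library totals as the only scaling, which moved the median log2 fold change of all genes from 0.16 to 0.50.

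**Figure D1:**
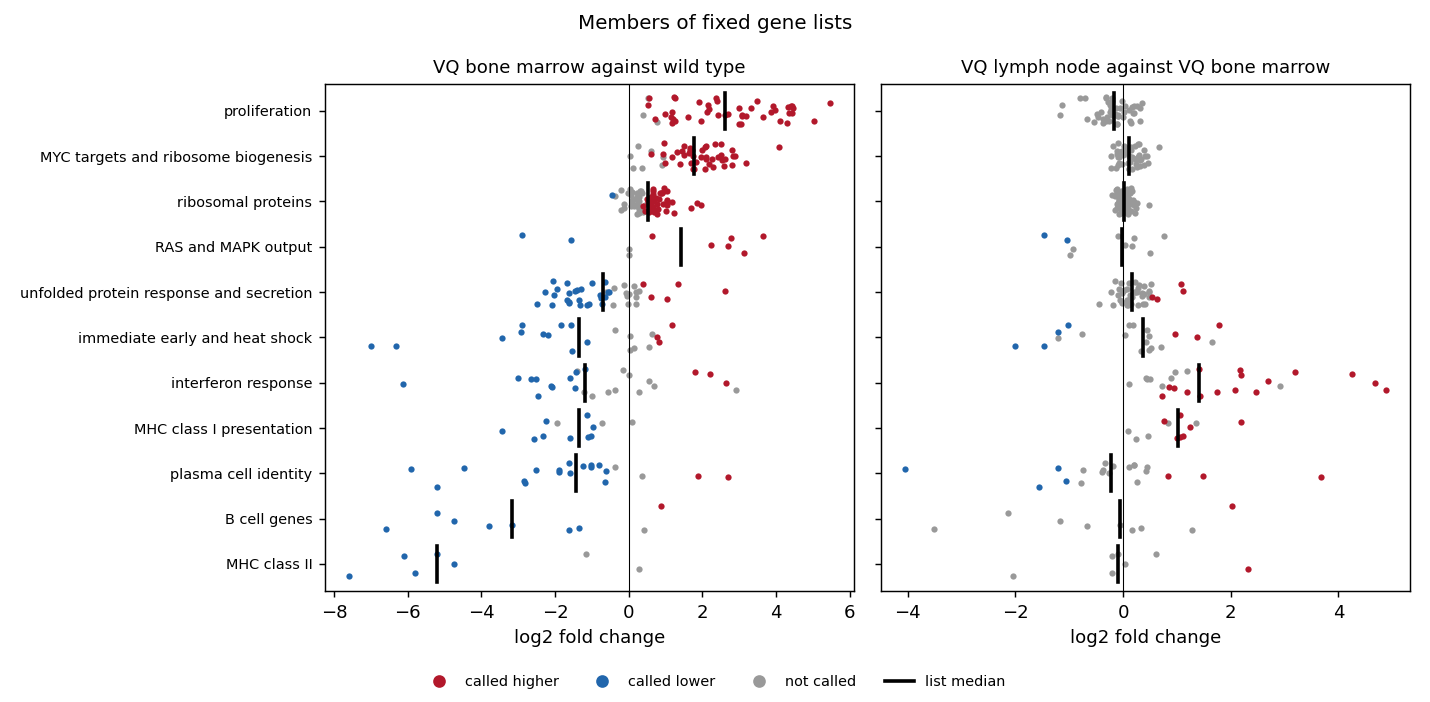
Log2 fold changes of the members of 11 gene lists in VQ bone marrow against wild-type bone marrow and in VQ lymph node against VQ bone marrow, each point a tested gene (a gene at 0 in a group is drawn at its bound) and each black bar the list's median. Proliferation genes (median 2.63 with genes at their bound) and MYC targets (1.77) lie above 0 in the first comparison, and interferon response genes (1.41) in the second.

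The second comparison sets VQ cells of the lymph node against VQ cells of the bone marrow. Interferon-induced genes and genes of MHC class I presentation were higher in the lymph node library, led by Gbp2, an interferon-induced GTPase, 26.1-fold higher. Mzb1 was 13.2-fold higher (log2 3.67, and 5.32 without the Jchain-rich cluster), and Il10, an immunoregulatory cytokine, 12.7-fold higher. Arg1, the arginase gene, was 7.97-fold lower, a call lost with the preset coefficient of variation. Myc, the MYC targets and the ribosomal proteins differed little. Of 8219 genes tested with edgeR, 126 were higher and 62 lower in the lymph node, 88 and 41 of them by at least 2-fold.

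Of 25 tested interferon response genes, 16 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.41, above all 10000 random lists. Gbp2 (chromosome 3, 142620602 to 142638008) stood at 8.80 ± 0.767 CPM (SD, n = 2) in VQ bone marrow and 223 CPM in the lymph node (log2 4.67, SE 0.32, edgeR adjusted p = 1.54e-44). The GTPases Gbp4 and Gbp7 were 19.8-fold (interval 10.7 to 40.9) and 6.48-fold (5.23 to 8.07) higher, and Ifi47 and Igtp, of the immunity-related GTPase family, 9.31-fold (6.54 to 13.6) and 5.51-fold (4.48 to 6.82). Among cells without cycle genes the calls of Gbp2, Gbp4 and Ifi47 were lost (log2 7.47, 3.34 and 1.74), and those of Gbp7 and Igtp were kept. The preset coefficient of variation gave the reverse, with the calls of Gbp7 and Igtp lost and those of Gbp2, Gbp4 and Ifi47 kept. Of 12 tested genes of MHC class I presentation, 7 rose and 0 fell (10 and 0 adjusted over the list alone; median 1.02, above all random lists). H2-K1 rose by 1.25 on the log2 scale, Psmb9, an immunoproteasome subunit, by 1.12, B2m by 1.06 and the peptide transporter Tap1 by 1.05. Psmb8, Psmb9 and Psma7 were the 3 proteasome genes of 48 that rose (0 fell; 4 and 0 adjusted over the list alone).

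Mzb1 stood at 108 ± 39.3 CPM (n = 2) in VQ bone marrow and 1261 CPM in the lymph node (log2 3.67, SE 0.18, edgeR adjusted p = 4.11e-85), against 5964 CPM in wild type. Its log2 fold change was 5.32 without the Jchain-rich cluster and 1.12 among cells without cycle genes. Among 20 tested plasma cell identity genes, 3 rose and 4 fell (4 and 8 adjusted over the list alone). Cd28, a costimulatory receptor also found on plasma cells, rose by 1.49 on the log2 scale, and Ly6c2 fell by 1.20. Jchain and Ikzf3, named here after their values were seen, fell by 1.06 and 1.57 (Jchain by 0.15 without the Jchain-rich cluster, not called), and Ly6k, named in the same way, rose by 0.83. Prg2 had no UMI in the lymph node and was at least 16.5-fold lower, and Slpi was 51.5-fold lower (interval 9.04 to 2057). Both calls were lost without the Jchain-rich cluster that holds wild-type and VQ bone marrow cells. Of 44 genes of the unfolded protein response and secretion, 4 rose and 0 fell (12 and 1 adjusted over the list alone). They were the chaperone Hspa5, by 0.53 on the log2 scale, Fkbp11 by 0.63, Sdf2l1 by 1.09 and Creld2 by 1.12. DESeq2 called 1 of the list, and the preset coefficient of variation and cells without cycle genes 0.

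Signals and surface genes differed one by one. Il10 (chromosome 1, 131019845 to 131024974) had 8 and 3 UMIs in the VQ bone marrow libraries and 74 in the lymph node (log2 3.63, edgeR adjusted p = 3.97e-16). It was 1 of 2 immune checkpoint genes of 10 that rose (0 fell; 3 and 0 adjusted over the list alone), the other being Ctla4, an inhibitory receptor named after its values were seen, 16.0-fold higher (interval 3.80 to 143) from 17 UMIs. Lifr, the receptor of leukaemia inhibitory factor, rose 4.42-fold (2.67 to 7.54) and the transcription factor Stat3 2.37-fold (1.69 to 3.32), among 3 of 19 cytokine receptor genes that rose (0 fell; 4 and 2 adjusted over the list alone). The remaining gene, the feedback inhibitor Socs1, was named after its values were seen and was 10.8-fold higher (3.70 to 43.0). Of 21 homing genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone): the adhesion molecule Icam1 rose by 1.34 on the log2 scale and Klf2, a regulator of lymphocyte trafficking, fell by 1.34. Cd63 rose by 2.13, and Ly6d, with 1 UMI in the lymph node, fell by 4.47 (both named after their values were seen). Without the Jchain-rich cluster the value of Ly6d was 2.81 and not called. Slc16a3, a lactate exporter, was 15.3-fold higher (7.32 to 36.9), and with Pkm and Aldoa it made up the 3 glycolysis genes of 17 that rose (0 fell; 3 and 0 adjusted over the list alone). Cyct, the testis form of cytochrome c, was 48.0-fold higher (12.6 to 407), Plac8 9.22-fold (5.66 to 15.8), Gbp5 18.1-fold (8.75 to 43.4) and Pet2 14.5-fold (8.09 to 28.1). Among cells without cycle genes the calls of Plac8 and Gbp5 were lost (log2 0.50 and 4.25).

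Arg1 (chromosome 10, 24915221 to 24927484) stood at 216 ± 35.2 CPM (n = 2) in VQ bone marrow and 28.5 CPM in the lymph node (log2 -2.96, SE 0.28, edgeR adjusted p = 2.82e-22). Fcer1g, the shared signalling chain of Fc receptors, was 11.2-fold lower (interval 5.98 to 23.7), and Abcd2, a peroxisomal transporter, 4.03-fold lower (2.69 to 6.27). Rnase2b, Hist1h2bc, Cirbp, Oaf, Dusp1, Slco5a1 and Ankrd28 fell by 1.88, 1.62, 1.58, 1.48, 1.46, 1.43 and 1.39 on the log2 scale. With the preset coefficient of variation, the calls of Arg1, Fcer1g, Abcd2 and every gene of the preceding sentence were lost. Those of Abcd2, Hist1h2bc, Oaf, Dusp1 and Ankrd28 were also lost with DESeq2. Immediate early genes split. In their list 3 of 20 rose and 4 fell (8 and 6 adjusted over the list alone), with Junb higher by 1.37 and Jun and Fos lower, at -1.20 and -1.02. Junb stood at -0.13 among cells without cycle genes, and its call was also lost with DESeq2. The call of Jun was lost among the same cells, and the preset coefficient of variation called 0 of the list. Hspa1b and Hsph1 rose by 1.78 and 0.97 and Fosb fell by 2.00, all named after their values were seen. Dusp1 and Etv5 were the 2 RAS and MAPK output genes of 10 that fell (0 rose; 0 and 3 adjusted over the list alone). Trp53inp1 and Pmaip1 were the 2 survival genes of 26 that fell (0 rose; 2 and 4 adjusted over the list alone). The call of Trp53inp1 was lost without the Jchain-rich cluster, where 2 survival genes of 24 rose and 1 fell.

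No tested proliferation gene or MYC target was called between the tissues. Myc stood at 1263 ± 95.3 CPM (n = 2) in VQ bone marrow and 1328 CPM in the lymph node (log2 0.08, SE 0.15, edgeR adjusted p = 0.908). Nras differed by 0.19 and Sdc1 by -0.25, neither called. Of 47 proliferation genes edgeR called 0 (0 higher and 2 lower adjusted over the list alone, 0 and 5 at unadjusted p under 0.05; median -0.16, percentile 0.18), and of 49 MYC targets 0 (0 adjusted over the list alone, 3 and 0 unadjusted; median 0.11, percentile 98.2). None was called with edgeR among 75 ribosomal protein genes (median 0.02), 73 oxidative phosphorylation genes (0.10), 29 myeloma oncogenes (-0.13), 22 integrated stress response genes (0.05) or 5 germinal centre genes (0.12), with 0 adjusted over the list alone in each. At unadjusted p under 0.05, in the same order, 1 and 0, 9 and 2, 1 and 1, 3 and 0, and 0 and 1 were higher and lower. DESeq2 called 0 in each of these lists. Of the proliferation genes, 2 were called lower without the Jchain-rich cluster, 2 with library totals without Jchain and 1 with library totals.

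Of 9 B cell genes, 1 rose (1 adjusted over the list alone), Irf8, and of 7 MHC class II genes, 1 rose (1 and 1 adjusted over the list alone, higher and lower), H2-Ob, both named after their values were seen. Irf8 stood at -1.38 among cells without cycle genes, not called. Gzma, a protease of T and NK cells, the 1 tested gene of that list and named after its values were seen, rose by 1.41 on the log2 scale (1 adjusted over the list alone), and the summed level of that list in the lymph node was 42.1 CPM. The macrophage and neutrophil lists had 3 and 1 tested genes and 0 calls with edgeR (0 and 1 adjusted over the list alone, 0 and 1 at unadjusted p under 0.05). DESeq2 called none in either. DESeq2 and the preset coefficient of variation also called none of the homing, cytokine receptor, RAS and MAPK output, survival, proteasome, B cell or MHC class II genes, and of the glycolysis and checkpoint lists 0 and 1 each. Of 3 sex-linked genes, 1 fell (1 adjusted over the list alone): Xist, the RNA of the inactive X chromosome, named after its values were seen, had 12 and 17 UMIs in the VQ bone marrow libraries and 0 in the lymph node.

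With a single lymph node library, DESeq2 called 13 higher and 9 lower genes, 5 of the interferon and 3 of the MHC class I list, a preset coefficient of variation of 0.4 gave 15 and 4, with 4 and 0 of those lists, all cells together gave 60 higher, and sums thinned to the smallest library 0 and 0 with edgeR (159 and 128 at unadjusted p under 0.05). Among cells without cycle genes (32 in the lymph node), 12 were higher and 24 lower, 3 interferon genes rose and 1 fell of 16 tested (median 1.01), and none of 10 MHC class I genes was called (median 0.17, against 1.02). The mix of cells may also change in this setting. The Jchain-rich cluster holds 23 and 21 VQ bone marrow cells and 0 lymph node cells. How many of them are among the 36 and 42 VQ bone marrow cells left was not counted. Values from cells without cycle genes therefore do not separate the cell cycle from cell mix or depth.

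**Figure D2:**
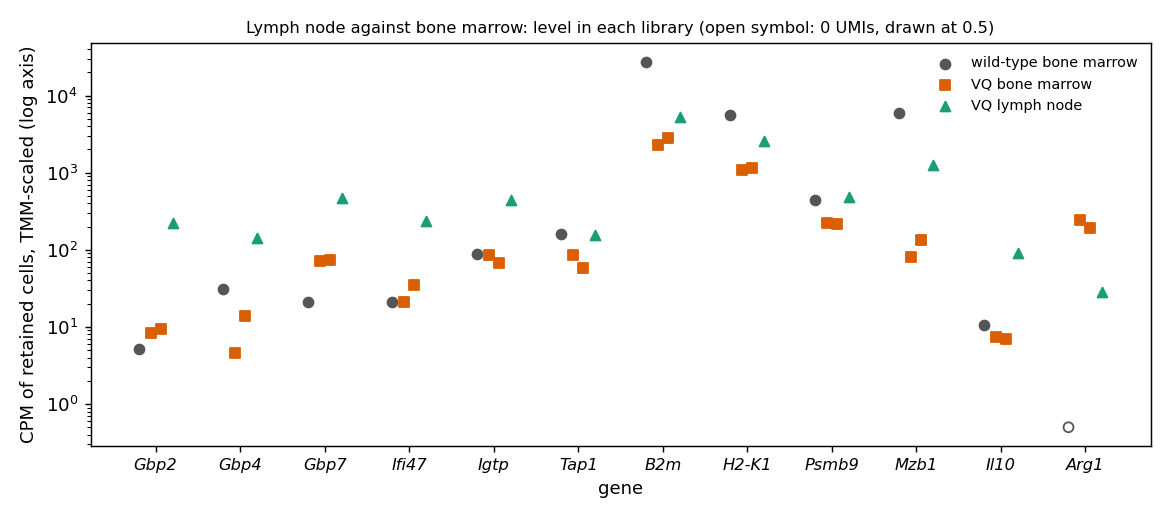
TMM-scaled CPM (log axis) of 12 genes in retained cells of each library, with an open symbol at 0.5 for a gene with 0 UMIs. Gbp2 lies at 8.80 CPM on average in VQ bone marrow and 223 CPM in the lymph node, and Mzb1 lies between its VQ bone marrow level (108 CPM) and its wild-type level (5964 CPM) in the lymph node (1261 CPM).

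The third comparison sets VQ cells of the lymph node against wild-type bone marrow cells sorted as plasma cells. It shares the wild-type library with the first, and tissue, genotype and possibly the sex of the animals differ at once. Myc was 31.8-fold higher (interval 16.1 to 73.9), Tex101 at least 49.0-fold higher, and proliferation and ribosome biogenesis genes rose, while Jchain was 46.1-fold lower (44.6 to 47.7). Interferon response genes went both ways. With edgeR, 1348 of 8219 genes were higher and 1056 lower, 1110 and 937 of them by at least 2-fold.

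Of 47 proliferation genes, 39 rose and 0 fell (42 and 0 adjusted over the list alone; median 4.05, or 2.34 with 16 genes at their bound), with Ccna2 at least 18.8-fold higher and Birc5 at least 10.7-fold. Of 49 MYC targets and ribosome biogenesis genes, 43 rose and 0 fell (44 and 0 adjusted over the list alone; median 1.91), and of 75 ribosomal protein genes, 41 rose and 0 fell (46 and 1 adjusted over the list alone; median 0.52). RAS and MAPK output genes rose in 6 of 10 and fell in 2 (7 and 2 adjusted over the list alone), with Phlda1 14.2-fold higher (interval 5.49 to 52.7) and Dusp1 and, named after its values were seen, Egr1 lower. Glycolysis genes rose in 8 of 17 and fell in 2 (8 and 2 adjusted over the list alone), with Slc16a1 at least 13.3-fold higher and Aldoa and Hif1a, named after their values were seen, lower. Myeloma oncogenes rose in 6 of 29 and fell in 7 (6 and 7 adjusted over the list alone), and Nras rose by 1.79 on the log2 scale, a call lost with the preset coefficient of variation, cells without cycle genes and thinned sums.

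Plasma cell identity genes fell in 14 of 20 and rose in 1 (14 and 2 adjusted over the list alone; median -1.18). Prg2 was at least 591-fold lower, Slpi, with 1 UMI in the lymph node, 5630-fold lower (interval 1009 to 222530), and Sdc1 fell by 0.86 on the log2 scale (edgeR adjusted p = 0.000344), a call lost with DESeq2, the preset coefficient of variation, cells without cycle genes, all cells and thinned sums. The gene that rose was Ly6c2, named after its values were seen, by 0.69. Secretion genes fell in 23 of 44 and rose in 7 (24 and 7 adjusted over the list alone, median -0.54), or in 16 and 11 with library totals (median -0.23), with Herpud1 5.60-fold lower (4.91 to 6.39) and Ssr2 7.53-fold higher (6.26 to 9.14). With the preset coefficient of variation the call of Herpud1 was lost and that of Ssr2 was kept. MHC class II genes fell in 5 of 7 and rose in 0 (5 and 0 adjusted over the list alone; median -4.95): H2-Aa, H2-Ab1, H2-Eb1, Cd74 and, named after its values were seen, H2-Ob. B cell genes fell in 7 of 9 and rose in 1 (7 and 1 adjusted over the list alone; median -2.51), Bach2, named after its values were seen (-0.77 with all cells, not called). With the clusters named plasma cell-like, 1 of 6 B cell genes fell and 0 rose (median -0.85). MHC class I genes fell in 5 of 12 and rose in 0 (5 and 0 adjusted over the list alone), with B2m at 27507 against 5271 CPM, beside Tapbp, Tap2, H2-T23 and, named after its values were seen, H2-K1. The median of that list was -0.17, and 0.15 with library totals as the only scaling. The calls of B2m, Tapbp, Tap2 and H2-T23 were lost with the preset coefficient of variation. Those of Tap2 and H2-T23 were also lost with DESeq2 and with the clusters named plasma cell-like. Interferon response genes rose in 10 of 25 and fell in 6 (12 and 6 adjusted over the list alone; median 0.22, or 1.25 without the Jchain-rich cluster). In this comparison, leaving out that cluster removes wild-type cells only. Gbp2 was 42.7-fold higher (7.58 to 1698), Gbp7 22.7-fold higher (8.79 to 83.7) and Ly6a 49.4-fold lower (38.3 to 64.7).

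Immediate early and heat shock genes fell in 12 of 20 and rose in 5 (12 and 5 adjusted over the list alone), with Fosb 44.0-fold lower (interval 22.2 to 99.2) and Ier2, Hspa8, Hspe1, Hsph1 and Hsp90ab1, named after their values were seen, higher. Survival genes fell in 10 of 26 and rose in 1 (10 and 1 adjusted over the list alone). Bcl2, with no UMI in the lymph node, was at least 42.1-fold lower, and the riser was Bak1, a pore-forming effector of apoptosis, 14.0-fold higher (2.42 to 563). The call of Bak1 was lost with DESeq2, the preset coefficient of variation, cells without cycle genes and thinned sums. Homing genes fell in 9 of 21 and rose in 4 (9 and 5 adjusted over the list alone), or in 8 and 7 with library totals, cytokine receptor genes fell in 4 of 19 and rose in 5 (4 and 5 adjusted over the list alone), and checkpoint genes fell in 4 of 10 and rose in 1 (4 and 2 adjusted over the list alone). Ly6d was 1061-fold lower (189 to 42075), Lifr at least 4.27-fold higher and Il10, the 1 checkpoint gene that rose, 8.79-fold higher (2.35 to 73.9). The checkpoint genes that fell were Btla and Pdcd1lg2 and, named after their values were seen, Lgals1 and Cd48. Epcam rose with Itgb1, Itga6 and Cd63, and Il5ra, Cd320, Socs1 and Socs2 rose beside Lifr (all but Epcam and Lifr named after their values were seen). Tnfrsf17, Il2rg, Tgfbr1 and, named after its values were seen, Jak1 (0.33 with the clusters named plasma cell-like, not called) were the cytokine receptor genes that fell. Integrated stress response genes rose in 5 of 22 and fell in 5 (9 and 5 adjusted over the list alone): Psat1, Phgdh, Psph, Shmt2 and Slc7a5 were higher, and Ddit3, Slc3a2, Ppp1r15a, Atf4 and Atf5 lower (Phgdh, Psph, Shmt2, Slc7a5, Atf4 and Atf5 named after their values were seen). The call of Psat1 was lost with DESeq2, the preset coefficient of variation, cells without cycle genes and thinned sums. With the preset the calls of Ddit3, Slc3a2 and Ppp1r15a were kept. Germinal centre genes rose in 2 of 5, Basp1 and Ung, and fell in 2, Fas and Mef2c (2 and 2 adjusted over the list alone). DESeq2 and the preset coefficient of variation called 0 of the 5. With the clusters named plasma cell-like both falls were lost, and Mef2c stood at 0.15. In energy and protein turnover, oxidative phosphorylation genes rose in 14 of 73 and fell in 7 (15 and 7 adjusted over the list alone), and proteasome genes rose in 13 of 48 and fell in 0 (13 and 0 adjusted over the list alone). With library totals the 2 lists gave 31 and 2 and 22 and 0 higher and lower genes, with DESeq2 3 and 0 and 0 and 0, and with the preset coefficient of variation none. Other changes included rises of Crygs (at least 18.4-fold), Cyp2b10 (at least 15.4-fold) and Fabp5 (at least 13.5-fold), and falls of Arhgdib (at least 180-fold), Chst1 (at least 139-fold), Rasgrp3 (at least 74.4-fold) and Serpina3g (at least 64.6-fold). Chst1, Rasgrp3, Slpi and Serpina3g rank among the top 10 genes of the wild-type cluster that also leads in H2-Aa. Ctss of the macrophage list (3 tested), S100a9 of the neutrophil list (1 tested) and Ddx3y and Eif2s3y of the sex-linked list (3 tested) fell, and Gzma of the T and NK list (1 tested) rose (S100a9 and Gzma named after their values were seen), with the same numbers adjusted over the list alone.

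DESeq2 called 207 genes higher and 224 lower in this comparison, a preset coefficient of variation of 0.4 gave 181 and 176, and the clusters named plasma cell-like alone 635 and 346, and sums thinned to the smallest library 0 and 1 with edgeR (894 and 877 at unadjusted p under 0.05). Of the calls, 56.1% were higher, a share that became 72.1% with library totals as the only scaling, which moved the median log2 fold change of all genes from 0.15 to 0.46.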

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

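All tests in this part were chosen after the result was seen. Xist, the RNA that marks an inactive X chromosome, was counted in cells outside the retained clusters of the VQ bone marrow libraries, in data that no comparison used: 13 UMIs among 43303 in replicate 1 and 3 among 54279 in replicate 2, against 0 among 113037 in wild type. The wild-type library holds Y-linked RNA, so its 0 may reflect the sex of that animal.

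Within the retained VQ bone marrow cells, too, Xist lay in the cells with at least 5% Jchain (22 of 29 Xist UMIs, 75.9%, interval 56.5 to 89.7), which hold 2.43% of the UMIs. Free RNA would spread these UMIs with depth, and cells carried over from the wild-type library would bring Y-linked UMIs, of which 0 were found where 11.1 would be needed (exact Poisson test p = 1.49e-05). Doublets with a myeloma cell would carry at least 50% of its Myc, while the upper limit in these cells was 22.03% of the level in the other retained cells. That value cannot decide on doublets, because the cells were chosen by at least 5% Jchain. A myeloma cell dilutes the Jchain of a doublet, so such doublets may lie among the other retained cells. Cells of the recipient animals may be a source: in the same libraries, cells of other types held Xist at 445 CPM without TMM scaling (interval 254 to 723, 32 cells), against an upper limit of 10.4 in the VQ cells with little Jchain. Whether recipients were female is not stated, and no biological explanation beyond this was tested.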

How the results depend on the processing

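No paired analysis was possible because the groups share fewer than 2 replicate numbers. Size factors, library totals with or without Jchain, no filter, doublet removal, cells of at least 1000 UMIs, removal of the cluster shared by wild type and VQ bone marrow and, for the 2 comparisons with VQ bone marrow, a fit of only their libraries left every count of higher or lower genes within 1.5 times its value. DESeq2 called fewer: 267 higher and 287 lower for VQ bone marrow against wild type, 13 and 9 for lymph node against VQ bone marrow, and 207 and 224 for lymph node against wild type, all among the genes reported. DESeq2 gave no adjusted p for 3506, 4940 and 3187 genes, and why the rest were fewer was not tested. The settings added after the data were seen were the preset coefficient of variation, the clusters named plasma cell-like, removal of the shared cluster, the minimum of 1000 UMIs and totals without Jchain. A preset coefficient of variation of 0.4 gave 252 and 280, 15 and 4, and 181 and 176, being wider than the 0.0819 estimated from the VQ bone marrow pair. Cells without cycle genes gave 251 and 306, 12 and 24, and 270 and 376, with 2813 genes left to test and 114, 36, 42 and 32 cells. Sums thinned to the smallest library gave 0 and 1, 0 and 0, and 0 and 1 with edgeR (unadjusted p under 0.05: 964 and 955, 159 and 128, 894 and 877), where the prior degrees of freedom fell to 2.17. Only clusters named plasma cell-like, with 51 wild-type cells, gave 614 and 372 for VQ bone marrow and 635 and 346 for lymph node against wild type. All cells of each table gave 60 higher genes for lymph node against VQ bone marrow. The prior degrees of freedom were 10.5 in that fit, in place of infinite, and whether this accounts for the fewer calls was not tested.

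Leiden resolution 0.5 gave a retained share of 80.4% in wild type, 96.3% and 96.3% in VQ bone marrow and 100% in the lymph node. The retained cells then numbered 131, 236, 181 and 185. In every library that equals the retained cells at resolution 1.0 together with the low-UMI and T cell-like cells. The share of cells with proliferation genes, in the order wild type, VQ bone marrow 1 and 2 and lymph node, was 34.8%, 91.7%, 86.0% and 88.0% with at least 1 gene, 0%, 62.6%, 55.0% and 54.4% with at least 3, and 40.8%, 93.7%, 86.8% and 97.5% without thinning, as a looser or stricter mark implies. Genes named by rule that changed direction, with a call in either setting, were Junb in the lymph node against VQ bone marrow (-0.13 among cells without cycle genes, adjusted p = 0.970 with edgeR), Lgals9 in the lymph node against wild type (-1.82 with all cells, adjusted p = 0.00145) and Mef2c in the same comparison (0.15 with clusters named plasma cell-like, adjusted p = 0.834). Of the genes named later, Ly6d and Irf8 (lymph node against VQ bone marrow), Dusp1, Bach2 and Jak1 (against wild type) did so in 1 setting each, not called there; the cause was not tested. Of the results for single named genes over all alternatives, 1413, 1368 and 1364 were counted as kept in the 3 comparisons, and 180, 147 and 199 lost the threshold. Kept means the same direction and side of the threshold or, in settings without a test, a move of no more than 1 SE. A sign change of a gene called in neither setting was counted as kept. In settings without a test, 120, 64 and 75 moved by more than 1 SE (85, 34 and 75 of these with the mean of per-cell CPM, the rest on leaving out a VQ bone marrow library). For the lymph node against wild type, leaving out either VQ bone marrow library kept all 107 results, but neither library is part of that comparison. Leaving out either VQ bone marrow library leaves no residual degree of freedom, so those are values without a test. Scrublet called 173 of 185 lymph node cells doublets, so that library was left as it was. The alternatives for dominant immunoglobulin genes were not run, since the tables hold none of those genes. Depth limits what a low count shows: with 227216 UMIs, 3 counts in wild type correspond to 13.2 CPM before TMM scaling.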

Other observations

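All tests in this part were chosen after the result was seen. The VQ bone marrow libraries hold 2 kinds of retained cell: 37 retained cells with at least 5% Jchain and 305 with less, a split on Jchain itself made after the data were seen. CPM in this part are relative to plain library totals, without TMM scaling. Myc stood at 116 CPM (interval 31.5 to 296) in the Jchain-rich cells and 1344 CPM (1283 to 1406) in the others, and Tex101, the germ cell glycoprotein, had 1 UMI against 986. Slpi went the other way, at 2601 CPM (2092 to 3197) against 5.03 CPM (2.02 to 10.4), as did Mzb1, at 2370 CPM (1885 to 2942) against 45.3 CPM (34.8 to 57.9). Arg1 had 1 UMI in the Jchain-rich cells and 344 in the others.

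Interferon genes were higher in the lymph node library (median log2 1.41). RNA of T cells like those captured here falls short of it. The T and NK cell list reached 44.1 CPM (interval 30.5 to 61.6), and T cell-like cells that brought the gain would bring 2978 CPM. That figure takes the ratio of T and NK cell to interferon RNA from 19 T cell-like cells, 1 of them from the lymph node. It cannot decide on lymph node T or NK cells with another ratio. The median without the cells shared with wild type was 1.63 with 19 genes called, and with the sums thinned to the same total UMIs it was 1.28, a setting in which edgeR called 0 genes of the whole comparison (159 higher and 128 lower at unadjusted p under 0.05). Between the 2 VQ bone marrow libraries the median was 0.0437. With 1 lymph node library, tissue is not separable from animal or library, and exposure to interferon in the lymph node may be one source.

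Mzb1 was low in VQ bone marrow and higher in the lymph node. Normal plasma cells that brought the Mzb1 of the lymph node library would bring 37312 Jchain UMIs at the wild-type ratio, and 3827 were counted. Without the Jchain-rich cells the bone marrow value was 45.3 CPM, against 1320 CPM in the lymph node. Cells with at least 500 UMIs were thinned to that number. Of these, 66 of 158 lymph node cells had Mzb1 (41.8%, interval 34.0 to 49.9), against 9 of 301 VQ bone marrow cells with little Jchain (2.99%) and 83 of 112 wild-type cells (74.1%). A difference between tissues, animals, clones or libraries could each give this, and 1 lymph node library does not separate them.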
